A study of Homo sapiens with 8 samples.

How the data were processed

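BEAS-2B is an established line of human bronchial epithelial cells, transformed with a virus. Per the labels, cells for RNA sequencing were transfected for 12 h with an expression plasmid carrying JunD or with the empty vector, and were then exposed to cigarette smoke extract (CSE) for 24 h. There were 3 libraries of each kind. Cells for chromatin immunoprecipitation (ChIP) were exposed to 8% CSE for 24 h, per the labels, and gave 1 library precipitated with a JunD antibody and 1 input library. The CSE concentration used for the RNA libraries is not given in the sources used here. The labels number the RNA libraries 1 to 3 in each group but do not say whether they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

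The authors deposited expression as RPKM, reads scaled to exon length and to the reads assigned in each library, in a table with the exon coordinates and summed exon length of 29534 gene names. Per the submitters' processing notes, which give no roles or order, the tools were Trimmomatic 0.36, STAR 2.5.3a, featureCounts from Subread 1.5.1, MACS2 2.1.1 and bedtools 2.25.0, with genome build GRCh38. The annotation release and the strand setting of the counting are not given in the sources used here. In each library, RPKM times exon length was a whole multiple of the value of 1 read for 100% of genes, within a tolerance of 0.01 read, so the reads per gene could be recovered. Assigned reads came to 16537306, 15967955 and 17725090 in JunD replicates 1 to 3 and to 17728754, 29617655 and 17871765 in empty-vector replicates 1 to 3. The authors' peak list, deposited with 61360 peaks, gives the position, a fold enrichment (a ratio over background), a linear p-value, a q-value and the pileup, a coverage signal at the summit, for each peak. Every listed peak had p below 0.01 and fold enrichment above 2. Peaks were called on the JunD library against the input library, per the labels, and the aligner of the ChIP reads is not given in the sources used here.

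Genes with a mean RPKM of at least 1 over the 6 libraries were tested with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(RPKM + 0.5), and were called at a Benjamini-Hochberg adjusted p below 0.05, two-sided. Fold changes are on the log2(RPKM + 0.5) scale, which understates the change of genes with low RPKM. Every adjusted p for a gene comes from limma. The script was checked on simulated reads for the JunD and empty-vector libraries, run over 12901 genes with 200 genes changed. It recovered 65.7% of genes changed by 0.5 on the log2 scale, 98.5% of those changed by 1 and 98.5% of those changed by 2, and 7.41% of its 189 calls were false, above the nominal 5% level. All genes were simulated with a common dispersion of 0.0023 and independently of each other. These rates may therefore not hold for noisier genes or libraries, such as JunD replicate 3, or for correlated genes. Gene lists, 27 in all, were fixed before the data were examined, and 566 of their 606 entries matched the table, 19 of them by an older symbol. Lists with 5 or more tested members were tested with limma's camera with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists, and again with the correlation estimated per list and with fry.

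The named genes follow a rule fixed before the data were examined. It takes JUND, the 10 protein-coding genes with the largest log2 fold change in each direction among called genes whose 3 libraries of each group do not overlap, up to 4 members of each tested list with the smallest p, any called member of smaller lists, 5 genes per direction with the smallest adjusted p among called genes with a peak within 1 kb of the start, the genes nearest to the 10 peaks of highest fold enrichment, and list genes of the AP-1, cytokine, NF-kB and matrix protease groups with a peak within 1 kb. The rule asks for protein-coding genes where a biotype is given and otherwise takes any gene with a name. Biotypes were matched for 21006 genes from a table of gene symbols, and gene names without a match were not taken as protein-coding, a reading settled after values were seen. The other reading would have added RP1-71H24.1 among the higher genes and AC068134.8, CTD-2319I12.2 and XXyac-YM21GA2.4 among the lower genes. Some genes that the rule takes are not reported here. Among the 112 genes taken by the rule that were tested, 14 share at least 20% of their exon length with another gene. Without a stated strand setting, the reads of such pairs cannot be told apart.

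A gene start was the 5′ end of the outermost exon, for the 29417 gene names at a single place and spanning at most 2500000 bp, and 117 names at several places were left out. Only the outermost start of each gene was used, so a peak at a distant inner promoter of a gene was not counted for that gene. Peak positions were compared with the same peaks shifted by 20, 50 and 100 kb either way, 6 shifts in all. Intervals of shares are exact binomial 95% intervals and cover counting error only. Promoter peaks of called and other tested genes were compared with a two-sided Fisher's exact test, and with a Cochran-Mantel-Haenszel test over 10 strata of mean expression. A search of the peaks for the AP-1 motif, planned before the data were examined, was not run, since no genome sequence was used here. Alternatives covered the pseudocount, the expression filter, scaling by median of ratios, to a fixed sum per library (TPM) or by quantiles, limma's trend and robust settings, a fold threshold, the replicate number as a block, each library left out, and stricter peak thresholds and other start windows. A limma-voom fit on the recovered reads, a fit without mitochondrially encoded genes, and peak sets with q below 0.1 or 0.05 were added after the data were examined. Tests used Python 3.11.15 with scipy 1.17.1.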

Results

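RNA was sequenced from BEAS-2B cells, a line of human bronchial epithelium, carrying extra JunD or the empty vector and then exposed to cigarette smoke extract, with 3 libraries per group. JunD binding was mapped by ChIP sequencing in smoke-exposed cells, with 1 precipitated and 1 input library. The RNA libraries held 15967955 to 29617655 assigned reads. The share of reads from mitochondrially encoded genes was 4.25% ± 0.44 (SD, n = 3) with JunD and 5.27% ± 0.05 (SD, n = 3) with the empty vector. The component holding 77.3% of the variance separated the groups. Along the component holding 11.8%, JunD replicate 3 stood apart from its group, at -22.2 against 11.7 and 10.8. Empty-vector replicates 1 to 3 lay at -8.39, -2.65 and 10.7, so this component spread both groups. Its cause was not tested.

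The series asks how JunD regulates the inflammatory response of airway cells to cigarette smoke, and the transfected gene was examined first. All libraries came from smoke-exposed cells, so a change with JunD cannot be told apart from one that would occur without smoke. JUND, an AP-1 transcription factor at chromosome 19, 18279760 to 18281622 on the minus strand (GRCh38), reached 78.8 ± 20.9 RPKM (SD, n = 3) with JunD against 11.4 ± 1.55 RPKM (SD, n = 3) with the empty vector, a log2 fold change of 2.71 with a standard error of 0.19 (limma adjusted p = 1.02e-04). All JunD libraries lay above all empty-vector libraries, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. RPKM values were 70.3, 63.5 and 103 with JunD and 13.2, 10.5 and 10.6 with the empty vector. The table does not separate plasmid from chromosomal transcripts.

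**Figure D1:**
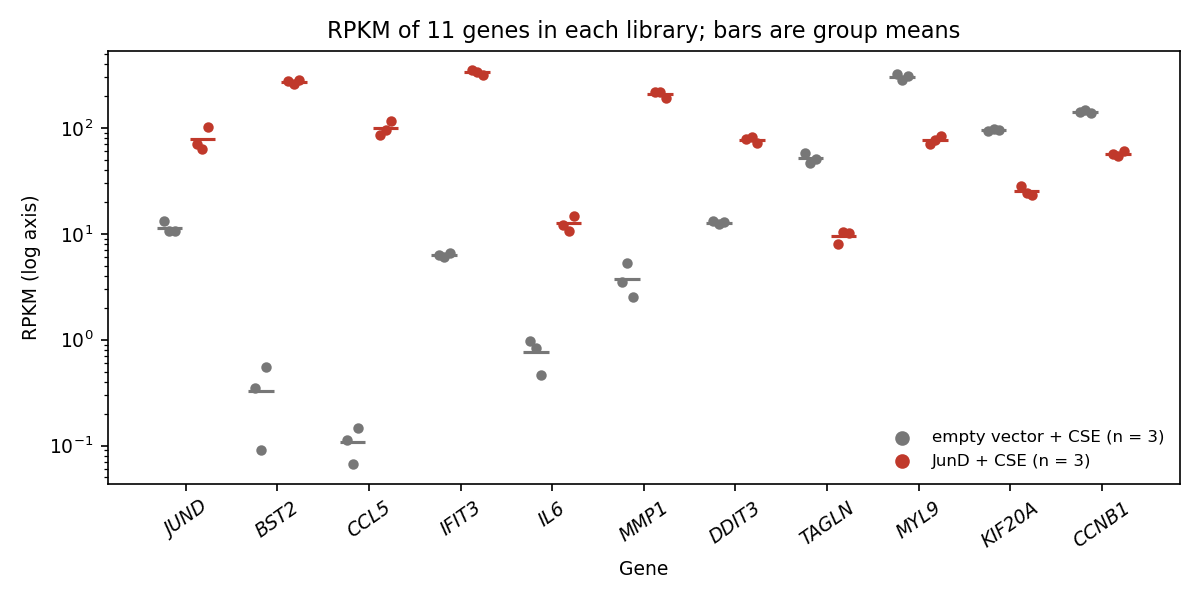
RPKM of 11 genes on a log axis, with a point for each library and a bar for each group mean, for empty vector with CSE (grey, n = 3) and JunD with CSE (red, n = 3). JUND, BST2, CCL5, IFIT3, IL6, MMP1 and DDIT3 lie higher in every JunD library, and TAGLN, MYL9, KIF20A and CCNB1 lie lower.

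Genes matched as protein-coding whose libraries did not overlap between groups were ranked by log2 fold change. Among them the largest rise with JunD was in BST2. This gene, whose product tethers budding virus to the cell surface (chromosome 19, 17402939 to 17405648), went from 0.331 ± 0.231 to 274 ± 12.96 RPKM (SD, n = 3 each), a log2 fold change of 8.41 with a standard error of 0.20 (adjusted p = 8.93e-07). IFITM1 rose by 7.60, and the T cell attractant CCL5 rose by 7.34, on the log2 scale, from 10 reads in the empty-vector libraries to 7564 in the JunD libraries. IFIT2 (5.93) and the collagenase MMP1 (5.67, from 3.78 ± 1.39 to 210 ± 15.8 RPKM) followed on the log2 scale, and then USP18 (5.64), IFIT3 (5.61), IFI44 (5.59), OAS1 (5.57) and OASL (5.43), which like BST2 and IFIT2 are on the interferon-stimulated list. Among the same genes the largest falls were in NPPB, which encodes a natriuretic peptide, at -2.76, in the actin-binding TAGLN at -2.39, from 52.1 ± 5.93 to 9.57 ± 1.37 RPKM, in the phosphatase ALPP at -2.17, in the myosin light chain MYL9 at -1.98 and in the mitotic kinesin KIF20A at -1.90. CNN1 (-1.75), MEST (-1.51), AP1M2 (-1.50), NT5DC2 (-1.49) and PALM3 (-1.49) were next. IFITM1 shares 32.5% of its exon length with IFITM2, and ALPP shares 20.6% with AC068134.8.

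Of 13379 genes tested, 4213 were higher and 1963 lower with JunD, and 487 and 110 of these changed at least 2-fold. Called genes whose libraries did not overlap between groups numbered 4195 higher and 1941 lower. Of all tested genes, 57.4% had groups that did not overlap, against 10% by chance. The split of calls depended on scaling, with 68.2% of calls higher in RPKM, 50.1% after median of ratios, 45.0% after quantile normalization and 76.9% in TPM. The median log2 fold change of all tested genes was 0.10 in RPKM, -0.0039 after median of ratios, -0.03 after quantile normalization and 0.18 in TPM, so small changes are relative to the scaling.

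Genes of the interferon response, which restrict viral growth, rose without exception among the members tested, 40 of 40, also when adjusted over the list alone and under each of the other scalings. Their median log2 fold change was 3.99 (camera adjusted p = 1.8e-30), and the call held with an estimated correlation (adjusted p = 0.033). MX2, a GTPase of the antiviral response, rose by 5.14 on the log2 scale, from 0.517 ± 0.022 to 35.3 ± 0.71 RPKM (SD, n = 3). Of 7 interferon genes listed, 3 were matched and 0 passed the expression filter, and those matched held 11 reads over the JunD libraries and 4 over the empty-vector libraries.

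Inflammatory cytokines and chemokines rose in 8 of 10 tested members and fell in 0, and adjusted over the list alone 10 rose. Besides CCL5, the log2 fold changes were 3.39 for IL6, 3.11 for IL24 and 1.67 for IL1B, with IL6 going from 0.758 ± 0.269 to 12.6 ± 2.099 RPKM (SD, n = 3). Feedback and response genes of NF-kB, a factor activated in inflammation, rose in 13 of 18 and fell in 0, with 13 also when adjusted over the list alone, among them TRAF1 (2.248), BIRC3 (1.91), TNFAIP3 (1.71) and ICAM1 (1.06). AP-1 subunits other than JUND rose in 10 of 13 and fell in 0, or 11 adjusted over the list alone, with BATF2 at 2.66, ATF3 at 2.46, MAFF at 1.84 and FOSL1 at 0.94. The camera adjusted p was 8.3e-05 for cytokines, 2.1e-04 for NF-kB genes and 2.6e-04 for AP-1, and these calls were lost with an estimated correlation, where the adjusted p was 0.25, 0.18 and 0.25.

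Immediate early genes outside AP-1, which respond within minutes to growth signals, rose in 16 of 20 and fell in 1, with 16 and 1 also adjusted over the list alone. KLF4 rose by 3.59, PHLDA1 by 1.41, DUSP6 by 1.19 and SPRY4 by 1.14. Genes of the unfolded protein and integrated stress responses, which act when protein folding or amino acid supply fails, rose in 20 of 27 and fell in 0, with 20 adjusted over the list alone, among them NUPR1 (2.89), DDIT3 (2.56), ASNS (1.62) and the factor ATF4 (1.21). Targets of p53 rose in 15 of 20 and fell in 0, with 15 adjusted over the list alone, among them the apoptosis genes PMAIP1 (3.23) and AEN (0.89), GDF15 (2.92) and TIGAR (0.57). Genes of matrix proteases and the plasminogen system rose in 12 of 16 and fell in 3, with 13 and 3 adjusted over the list alone, where SERPINB2 reached 3.75, MMP3 2.86 and PLAU 2.03. The camera adjusted p was 6.2e-05, 1.1e-05, 4.6e-04 and 0.0035 for these lists in turn, and with an estimated correlation the adjusted p was 0.31, 0.12, 0.31 and 0.25, past no threshold.

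Mitotic genes fell in 27 of 30 tested members and rose in 0, or 28 adjusted over the list alone, with a median of -0.71 (camera adjusted p = 2.1e-17, and adjusted p = 0.12 with an estimated correlation). After KIF20A came CCNB1, a cyclin that drives entry into mitosis, at -1.32, from 143 ± 4.84 to 57.1 ± 2.63 RPKM (SD, n = 3), AURKA at -1.01 and CCNB2 at -0.87. DNA replication genes rose in 9 and fell in 2 of 30, the same counts adjusted over the list alone, with RPA2 at 0.75, GINS3 at 0.61, CCNE2 at 0.46 and CDC6 at 0.38, and the list was not called (camera adjusted p = 0.67). The lean of the replication genes depended on scaling, with 5 higher and 6 lower after median of ratios and 6 and 4 after quantile normalization, and 5 were higher without empty-vector replicate 2.

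Mesenchymal and matrix genes fell in 10 and rose in 6 of 24, or 11 and 7 adjusted over the list alone, and the log2 fold change was -1.40 for THBS1, -0.96 for TGFB2 and -0.71 for FN1. Epithelial junction and keratin genes fell in 5 and rose in 2 of 13, or 6 and 2 adjusted over the list alone, with KRT8 at -0.65, PKP2 at -0.65, KRT18 at -0.38, a call lost in 3 of the 6 fits that leave out a library and with the replicate block, and CLDN1 at 0.83. Antioxidant genes of the NRF2 pathway fell in 10 and rose in 4 of 24, the same adjusted over the list alone, with AKR1B10 at -0.996, EPHX1 at -0.83, TKT at -0.74 and AKR1B1 at -0.69. Heat shock proteins fell in 7 of 19 and rose in 0, also adjusted over the list alone, with HSPA8 at -0.43, STIP1 at -0.41, HSP90AA1 at -0.54 and HSPB1 at -0.73, the last 2 of which lost their calls in 1 and 4 of the 6 fits that leave out a library, without the expression filter and with the block. After median of ratios 10 heat shock proteins fell, and in TPM 4 fell and 1 rose. With a library left out 2 to 7 fell, and without JunD replicate 3 CHORDC1 and DNAJB4 rose. Of the epithelial genes 2 to 5 fell with a library left out, and that list lost its call in 3 of these fits. The camera adjusted p was 0.0047, 0.047, 0.0035 and 9.0e-04 in turn, and with an estimated correlation the adjusted p was 0.34, 0.25, 0.41 and 0.25.

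Cytosolic ribosomal proteins fell in 13 of 50 and rose in 0, or 6 adjusted over the list alone, with RPL7A at -0.43 and RPS3A at -0.39, RPL3 at -0.35 and RPS6 at -0.30 (camera adjusted p = 1.0e-05, and adjusted p = 0.49 with an estimated correlation). After median of ratios 28 ribosomal proteins fell, and in TPM 6. With a library left out 5 to 24 ribosomal proteins fell, with 24 without JunD replicate 3. Cholesterol genes fell in 8 and rose in 4 of 23, also adjusted over the list alone, with ACAT2 at -0.58, INSIG1 at -0.40 and STARD4 at 0.55 (camera adjusted p = 0.035, and adjusted p = 0.49 with an estimated correlation). After median of ratios 9 fell and 2 rose, after quantile normalization 8 and 1, and in TPM 6 and 4. The median of the list was -0.071 in RPKM and -0.0016 in TPM. With a library left out 4 to 10 cholesterol genes fell, and the list lost its call in 3 of these fits. Mitochondrially encoded genes fell in 5 and rose in 2 of 15, also adjusted over the list alone, with MT-CO3 at -1.13, MT-ATP6 at -0.94, MT-ND3 at -0.92 and MT-ATP8 at -0.72, while the ribosomal RNAs MT-RNR2 at 1.22 and MT-RNR1 at 1.12, named after their values were seen, were the 2 that rose (camera adjusted p = 0.0089, and adjusted p = 0.49 with an estimated correlation). The median of the mitochondrial list was -0.16 in RPKM, -0.28 after median of ratios and -0.09 in TPM, and turned to 0.07 only after quantile normalization. That method gives all libraries the same value at each rank, so a gene that keeps its rank shows no change. After quantile normalization MT-CO3 was at -0.648, and MT-ATP6 at -0.28 and MT-ATP8 at 0 were no longer called, and neither was called without the expression filter. Glycolysis and hypoxia genes went both ways, 7 higher and 9 lower of 25, or 7 and 10 adjusted over the list alone, with VEGFA at 1.87, SLC2A3 at 0.81, HK2 at 0.49 and LDHA at -0.81 (camera adjusted p = 0.089). Of 6 replication-dependent histones tested, HIST1H2AC rose by 0.58 and HIST1H1C fell by 0.81, also adjusted over the list alone (camera adjusted p = 0.27), while HIST1H2BJ had -0.38 (adjusted p = 0.15) and HIST1H2BD 0.13 (adjusted p = 0.18).

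**Figure D2:**
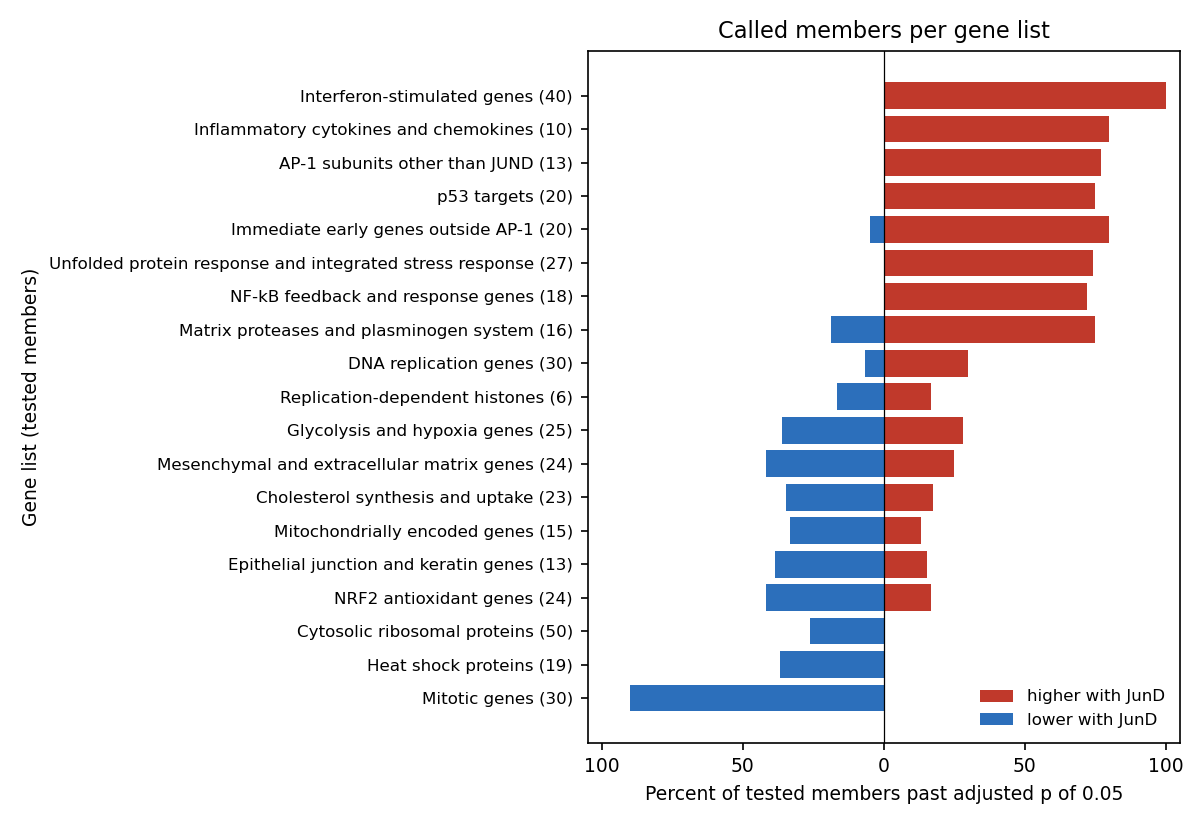
Percent of tested members of each gene list called higher (red, to the right) or lower (blue, to the left) with JunD, with the number of tested members in brackets. Interferon-stimulated genes were higher in 40 of 40 members and mitotic genes lower in 27 of 30, in RPKM. The median of the mitochondrially encoded list was negative in RPKM, after median of ratios and in TPM, and positive only after quantile normalization.

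In lists too short to test as sets, metallothioneins rose in 3 of 3 tested, with MT2A at 0.98, MT1E at 0.60 and MT1X at 0.37, although MT1X was lost without JunD replicate 2 and without empty-vector replicate 1 or 3 (adjusted p = 0.053, 0.056 and 0.057) and after quantile normalization. MT1E was lost without empty-vector replicate 3, and close paralogs can share reads. Of the aryl hydrocarbon receptor list, NFE2L2 rose by 0.50 and AHRR fell by 0.32, with 4 tested. The AHRR call was lost in 5 of the 6 fits that leave out a library, without the expression filter, with the replicate block and in TPM. Markers of other cell types were mostly below the filter. CD68, of the leukocyte list, rose by 2.15 and shares 81.7% of its exon length with RP11-186B7.4, TUBA1A, of the ciliated, club and alveolar list, fell by 0.96, and PDGFRB, of the fibroblast list, fell by 0.94. No mucin or endothelial marker reached the filter. Of the 19 lists tested, 16 passed with the preset correlation and 1, the interferon-stimulated list, with an estimated correlation. Other named genes that share at least 20% of their exon length with another gene were IL6, DDIT3, PLAU, ICAM1, DUSP6, CCNE2, ACAT2, TGFB2 and MT-ATP8.

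The ChIP comparison asked where JunD lay in smoke-exposed cells. Of the 10 peaks of highest fold enrichment on the main chromosomes, 2 lay in pseudogenes of actin genes, ACTG1P23 on chromosome 3 (175977450 to 175977872, fold enrichment 10.6) and ACTBP8 on chromosome 6 (88275914 to 88276375, fold enrichment 8.36), whose sequence resembles that of other genes. Between them ranked a peak on chromosome 14 (17160353 to 17160630, fold enrichment 9.37), whose nearest start, that of ARHGAP42P5, lay 1466 kb away. Starts nearest to the rest of the top 10 were those of AC007389.1 (150 kb away), ARPC3P5 (39.9 kb), RBBP4P4 (443 kb) and RP5-878I13.2 (6.71 kb). Also among them were MYL2 (3.02 kb), RP11-72I2.2 (92.5 kb) and TMEM178B (209 kb), of which MYL2 and TMEM178B held the peak within the gene. A nearest start alone does not link a peak to a gene. Within 1 kb of a start in the AP-1, cytokine, NF-kB and matrix protease lists, peaks lay at genes including JUN, FOSL2, MAFF, CXCL1, CCL26, RELB, TRAF1, MMP2 and MMP14, with the authors' fold enrichment from 2.11 at TRAF1 to 3.90 at MMP14 and q-values from 0.072 at MMP14 to 0.58 at TRAF1. No peak lay within 5 kb of the start of JUND.

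The authors' list held 61360 peaks with a median width of 251 bp, a median fold enrichment of 3.12 and a median pileup of 5, and fold and q are the authors' values for each peak. Peaks with q below 0.05 numbered 1596, or 2.60%. Of all peaks, 49.4% lay between genes, 47.4% in a gene beyond 1 kb of a start, and 3.15% (exact 95% interval 3.01 to 3.29) within 1 kb of a start, against a mean of 2.72% for shifted peaks (range 2.62 to 2.77). Among peaks with fold enrichment of at least 5 the share was 8.39% (5.40 to 12.3), against 3.35% when shifted. For all peaks within 5 kb of a start the direction turned, with 9.90% against 10.7% when shifted. There is no replicate of either ChIP library.

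**Figure D3:**
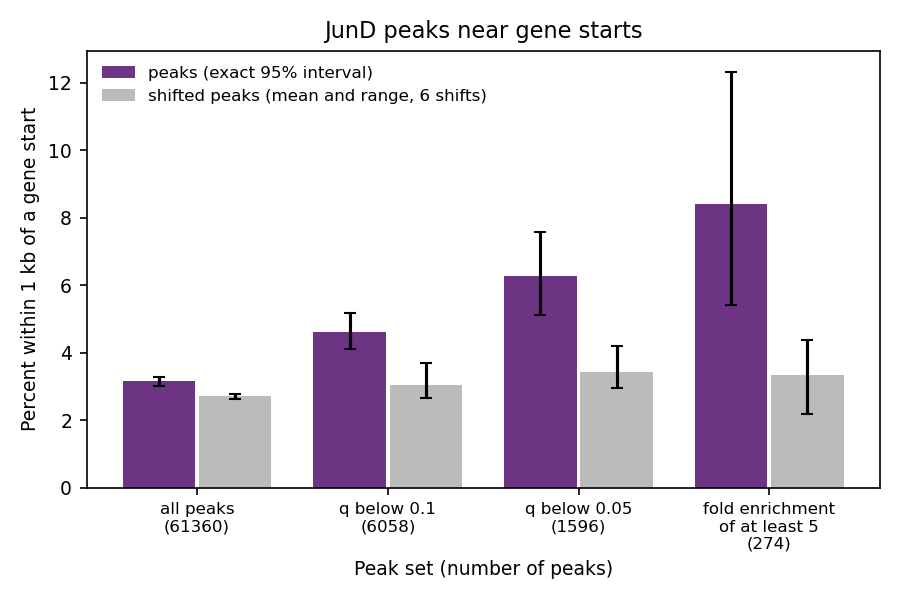
Percent of JunD peaks within 1 kb of a gene start (purple, exact 95% interval) and of the same peaks shifted (grey, mean and range of 6 shifts), for all 61360 peaks and for peaks with q below 0.1, q below 0.05 or fold enrichment of at least 5. The share was 3.15% for all peaks and 8.39% at a fold enrichment of at least 5.

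The last comparison asked whether genes with a JunD peak at the start were those that changed. The labels give no transfection for the ChIP cells and no CSE concentration for the RNA cells. Peaks and changed genes may therefore come from cells with unlike JunD levels or smoke doses. Of genes with a mean RPKM of at least 1, 7.43% had a peak within 1 kb of the start, against a mean of 6.49% for shifted peaks. Of genes below 1 RPKM, the shares were 7.07% and 6.12%. Of all listed peaks, 90.1% had q of 0.1 or more. A peak at a named gene is therefore little evidence of binding on its own. Called genes with a peak included the RNA sensor IFIH1 (log2 fold change 4.45), TRIM22 (4.53), AC009950.1 (2.60) and MAFF among the higher genes, and NPPB, FAM101B (-1.28), CTD-2510F5.6 (-1.01), the gelatinase MMP2 (-0.91) and FAM171A1 (-1.03) among the lower genes. Of the list genes with a peak, RELB (1.26), CXCL1 (1.01), MMP14 (0.51), JUN (0.36) and FOSL2 (0.25) also rose. FOSL2 was lost after median of ratios (0.13, adjusted p = 0.091) and quantile normalization (0.15), without the expression filter, with the replicate block and in 3 of the 6 fits that leave out a library. CCL26 was below the filter. AC009950.1 lies wholly in exons of SP110, and CTD-2510F5.6 shares 75.8% of its exon length with SMG8. A peak lay within 1 kb of the start of 419 of 6170 called genes (6.79%) and of 573 of 7186 others (7.97%), an odds ratio of 0.841 (95% interval 0.738 to 0.958, Fisher's exact p = 0.0098). The odds ratio was 0.835 for higher genes (Fisher's exact p = 0.017) and 0.852 for lower genes (p = 0.12), and 0.840 over strata of expression (Cochran-Mantel-Haenszel p = 0.0094). It lay between 0.921 and 1.12 for the 6 sets of shifted peaks. The call was lost without empty-vector replicate 3, at 0.889 (Fisher's exact p = 0.089), within 500 bp, at 0.888 (Fisher's exact p = 0.15), and with peaks of q below 0.1, at 0.763 (Fisher's exact p = 0.078). With peaks of fold enrichment of at least 5 the ratio turned to 2.33 (Fisher's exact p = 0.25). The median log2 fold change was 0.09 for the 992 genes with a peak and 0.10 for the others (camera p = 0.78, and p = 0.92 with an estimated correlation), and genes are not independent replicates.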

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

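Tests in this part were chosen after the results were seen, except that the rescalings and the test over strata of expression were planned and the count over splits of the libraries was a fixed check. Genes left out of the comparisons for low expression were searched for 10 or more reads in each JunD library and 0 in all empty-vector libraries, and 4 were found. They were ZBP1, a sensor of nucleic acids, with 80 reads over the JunD libraries, ZBTB32 with 65, the chemokine CXCL11 with 62 and AC004988.1 with 33. Against a floor of 3 reads over the empty-vector group, these levels are at least 34.6-fold, 28.1-fold, 26.8-fold and 14.3-fold higher. No gene showed the reverse.

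The rise of interferon-stimulated genes was weighed against technical explanations. Scaling is argued against by the list's lowest median log2 fold change over RPKM and the other scalings, 3.86. RNA from leukocytes stays open. The 8 leukocyte markers matched held 19188 reads with JunD and 5633 with the empty vector, a ratio of shares of 4.42 (4.29 to 4.56), of which CD68, which many other cells express, held 19139 and 5527. The other markers, near the floor, held 49 and 106, and 6 of the 8 took a smaller share with JunD, so the list does not decide it. A stronger response to the JunD plasmid than to the empty vector cannot be told apart from an effect of the JunD protein, since the groups differ in the plasmid and no other insert was compared, and the 7 reads of IFNB1 and IFNL1 in the JunD libraries do not decide it.

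The excess of higher calls, 68.2% (67.0 to 69.4), was weighed likewise. The lower mitochondrial share in the JunD libraries is argued against as the whole cause, since 66.3% (65.1 to 67.5) of calls were higher without mitochondrially encoded genes. Scaling to the total of assigned reads stays open. The 50.1% found after median of ratios decides nothing, because that scaling centres the fold changes. No biological explanation of the split was tested.

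The share of peaks within 1 kb of a start, 3.15%, was 1.16 times the mean of shifted peaks. Within 5 kb it was 9.90%, below the 10.7% of shifted peaks. The odds ratio of a peak at called genes was 0.841, and that call was lost within 500 bp, with peaks of q below 0.1 and without empty-vector replicate 3, and the ratio turned to 2.33 with peaks of fold enrichment of at least 5. Weak enrichment in the precipitated library, with most listed peaks near background, may account for the small excess within 1 kb, since 6.27% of peaks with q below 0.05 lay within 1 kb of a start (exact interval 5.13 to 7.57), above both the whole list and the highest shifted share of 4.20%. Starts of pseudogenes counted as starts, and the peaks in ACTG1P23 and ACTBP8 lay 0.698 and 0.614 kb from theirs. Placement of reads in sequence that resembles other genes was not tested and stays open. It could also raise the share near starts among peaks of low q, so that share cannot tell it from weak enrichment. Mean expression is argued against as the cause of the lower odds over all peaks, since the odds ratio over strata was 0.840 (0.737 to 0.958). Binding of JunD away from gene starts was not tested and stays open.

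Of the 10 splits of the 6 libraries into groups of 3, the real split alone gave as many genes (1 of 10), with 6176 genes against 0 at most in the others, which held 63 to 1373 genes at an unadjusted limma p below 0.05. The 1373 came from the split that sets JunD replicates 1 and 2 and empty-vector replicate 3 against the rest. The next highest was 146. The component holding 11.8% of the variance divides the libraries the same way as the split with 1373. For gene lists under the preset correlation the real split gave 16 and the highest other 13, again 1 of 10. So few splits cannot give a share under 0.1. Other splits still set 2 JunD libraries against 1, so they hold part of the difference. That difference also widens the spread within their groups, so their 0 called genes do not measure chance.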

How the results depend on the processing

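The voom fit, the fit without mitochondrial genes and the peak sets by q were added after the data were seen. JUND stayed called in every alternative, at 2.502 to 2.85 with a library left out. Genes called higher fell from 4213 to 2334 with a filter at 5 RPKM (fewer genes tested), 2657 after quantile normalization and 487 at 2-fold or more. Genes called lower went from 1963 to 3014 after median of ratios, 3244 after quantile normalization, 1188 with the replicate number as a block and 110 at 2-fold or more. After removal of group means, correlations between the groups were -0.17, -0.08 and -0.38 for libraries of the same number. They were -0.24 to 0.31 for libraries of different numbers. These values gave no sign of pairing, but so few libraries cannot exclude it. The block left 2810 genes higher, with AHRR, FOSL2, HSP90AA1, HSPB1, KRT18 and MT1X no longer called. With a library left out, 3148 to 4322 genes were higher and 1335 to 2651 lower. Voom called 4482 higher and 2090 lower. Called lists fell from 16 to 1 with an estimated correlation and numbered 14 to 16 with a library left out. Peaks numbered 13 at −log10 q of at least 5, 274 at fold enrichment of at least 5 and 1596 at q below 0.05, and the share near a start was 23.1%, 8.39% and 6.27% in turn. It was 1.98% within 500 bp and 9.90% within 5 kb, where shifted peaks gave 10.7%. The 3 peaks within 1 kb at −log10 q of at least 5 included those in the pseudogenes ACTG1P23 and ACTBP8. The odds ratio of a peak at called genes was 0.888 within 500 bp (Fisher's exact p = 0.15), 0.763 at q below 0.1 (p = 0.078), 0 at −log10 q of at least 5, where 1 tested gene had a peak (p = 1), and reversed to 2.33 at fold enrichment of at least 5, with 12 genes (p = 0.25). With a library left out it was 0.808 to 0.889. The difference in median fold change of genes with a peak was -0.0209 to -0.0068 with a library left out, and could not be tested at −log10 q of at least 5. The cause of these changes was not tested except where given. The AP-1 motif search and its alternatives were not run. Depth limits genes with few reads, such as NPPB with 6 reads over the JunD libraries. With a library left out, calls were lost for AHRR in 5 of the 6 fits (all but the fit without JunD replicate 3), for HSPB1, KRT18, FOSL2 and MT1X in 4, 3, 3 and 3 fits, and once each for HSP90AA1 (without empty-vector replicate 2) and MT1E (without empty-vector replicate 3), with the direction kept. Without the expression filter AHRR, FOSL2, HSP90AA1, HSPB1, MT-ATP6 and MT-ATP8 were no longer called, and after quantile normalization FOSL2, MT1X, MT-ATP6 and MT-ATP8 (the last alone at 0 change) were not, while HIST1H2BJ was. The epithelial list was lost at a pseudocount of 0.1, with the block and in 3 fits that leave out a library, and the cholesterol list in 3 such fits and with fry. Fry also lost the ribosomal list and called DNA replication, and the glycolysis list was called at a filter of 5 RPKM.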

Other observations

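Gene lists in this part were written after values were seen, so their tests are not independent evidence. Genes of antigen presentation by class I molecules rose in 19 of 19 tested members, with a median log2 fold change of 1.32 (camera adjusted p = 1.1e-10, and adjusted p = 0.063 with an estimated correlation). Actomyosin genes, which build the contractile apparatus, fell in 17 of 21 and rose in 1, with a median of -0.54 (adjusted p = 6.7e-11, and adjusted p = 0.022 with an estimated correlation). Aminoacyl-tRNA synthetases rose in 11 and fell in 2 of 18 (adjusted p = 0.026, and adjusted p = 0.090 with an estimated correlation). Nucleic acid sensors and their adaptors rose in 9 and fell in 2 of 11 (adjusted p = 0.0082, and adjusted p = 0.090 with an estimated correlation). A list of serum amyloid A and serpin genes, put together from genes already seen to be high, rose in 5 of 5 (adjusted p = 4.1e-05), which its choice made nearly certain.

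Several inflammatory genes below the expression filter had reads in both groups. CXCL8, a neutrophil attractant, had 57, 61 and 62 reads with JunD and 11, 27 and 14 with the empty vector. CSF2 had 40 reads with JunD and 1 with the empty vector, and CXCL2 had 64 and 9. CCL2 had 7 and 24 reads, 15 of the latter in empty-vector replicate 2, and was not called without the filter (limma adjusted p = 0.29). Peaks were sparse on chromosomes 4 (10.8 per Mb), 13 (12.96 per Mb) and X (7.56 per Mb), against a median of 22.5 per Mb over the other autosomes. These chromosomes also held few genes, 5.26, 5.53 and 6.55 per Mb. Chromosome 18, with 6.26 genes per Mb, held 18.1 peaks per Mb. The cause of the sparse peaks was not tested.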
